A study of Mus musculus with 3 samples.

How the data were processed

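RNA was measured in single droplets (10x Genomics) from ventricular tissue of C57B6 mice, which had been kept frozen. Whether whole cells or nuclei were loaded is not given in the sources used here, and this bears on what shares of cells, Malat1 and mitochondrial RNA mean. There were 3 libraries and each held 3 pooled hearts, per the labels. The groups were Sham with vehicle, TAC with vehicle, and TAC with artesunate (TAC+ART). TAC is transverse aortic constriction, a narrowing of the aorta that puts a pressure load on the left ventricle. Artesunate is a drug of the artemisinin family used against malaria. The authors deposited raw UMI counts per gene and barcode for each library, with no normalization. Per the submitters' processing notes, reads were processed with Cell Ranger and Seurat on the mm10 build, and tool versions and the gene annotation are not given in the sources used here. The matrices hold 29994 gene symbols and 18021 barcodes. They had been filtered before deposit, since few barcodes reach 10000 UMIs while many lie just under it, and the rule is not given in the sources used here. Gene positions were taken from GENCODE M21 on the same build (GRCm38), which holds 28522 of the symbols.

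Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 2 Sham barcodes, 1 TAC barcode and no TAC+ART barcode. Doublets were scored per library with an own implementation of Scrublet's score, with 2 simulated doublets per barcode, 2000 variable genes and 30 principal components. The top 0.8% per 1000 barcodes was removed, which took 112 Sham, 440 TAC and 376 TAC+ART barcodes (2.99%, 5.94% and 5.48%). The 17090 cells left were 3638 in Sham, 6972 in TAC and 6480 in TAC+ART.

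Counts were scaled to 10000 per cell and log transformed, and the 3 libraries were clustered together without integration on 3000 variable genes and 30 components, with a graph of 20 shared neighbours and the Leiden method at resolution 1 (seed 1). A cluster was named after a class, as "fibroblast-like", where at least 3 of the class's fixed markers lay 2-fold or more above the median cluster. It stayed unnamed where another, unrelated class scored at least 0.7 times as high or held more markers among the 10 leading genes. Classes counted as related were endothelial, endocardial and lymphatic endothelial, then pericyte and smooth muscle. Cardiomyocyte and atrial cardiomyocyte were related too, as were macrophage, monocyte and dendritic. The endocardial-like cluster was thus named at a score of 3.229 although endothelial markers scored 2.634. Of 28 clusters, 3 stayed unnamed. The fixed markers of the classes reported were as follows. Fibroblast used Pdgfra, Dcn, Col1a1, Col1a2, Col3a1, Lum, Gsn, Tcf21, Abca8a and Dpt. Cardiomyocyte used Ttn, Ryr2, Myh6, Tnnt2, Actc1, Myl2, Myl3, Tnni3, Pln and Ctnna3. Endothelial used Pecam1, Cdh5, Flt1, Kdr, Ptprb, Egfl7, Emcn, Cyyr1 and Tie1. Macrophage used Mrc1, F13a1, Csf1r, Adgre1, C1qa, C1qb, C1qc, Cd163, Ms4a7 and Cd68. Pericyte used Pdgfrb, Rgs5, Abcc9, Kcnj8, Vtn, Notch3 and Cspg4 among its 8 markers.

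UMIs were summed per class and library and divided by the class total, giving CPM. Ratios are log2 values with 0.5 counts added to each sum. The main comparisons were TAC over Sham and TAC+ART over TAC in fibroblast-, cardiomyocyte-, endothelial- and macrophage-like cells. With 1 library per group there was no test. Shares carry exact Clopper-Pearson intervals, sums exact Poisson intervals and ratios of sums exact conditional binomial intervals, all at 95% and all covering counting error only. Ratios of shares have delta-method intervals on the log scale, and medians of lists and of chosen genes have intervals from 400 and 200 Poisson redraws of the counts.

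Genes were named by size. Genes with at least 100 UMIs in the 2 libraries together and 50 CPM in the higher one were ranked by ratio, and the 10 highest and 10 lowest in fibroblast-like cells, and the 5 highest and 5 lowest in the other 3 classes, were named, except for 1 fibroblast-like gene that is not reported here. Mitochondrial, ribosomal, haemoglobin and sex-linked genes, Malat1, markers of another class, and genes more than 10-fold below the class where they are highest were left out. Ly96, Tlr4, Cd14, Postn, Col1a1, Col3a1, Nppa, Nppb, Myh6 and Myh7 were always named, and so were up to 4 members of each list per ratio, the 2 highest and the 2 lowest. The 20 fixed lists cover fibrillar collagen and matrix, activated fibroblast, resting fibroblast, the TLR4 and MD2 pathway, NF-kB target genes, TGF-beta signalling, the hypertrophy programme, adult contraction and ion handling, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, glycolysis, resident and recruited macrophage, interferon response, endothelial activation, capillary endothelial, iron, haem and ferroptosis, the unfolded protein and integrated stress response, cell cycle, and immediate early and heat shock genes. A further 4 lists describe RNA quality and free RNA, which are mitochondrially encoded, haemoglobin, cardiomyocyte RNA outside cardiomyocytes, and sex-linked genes. A member counted as measured with at least 20 UMIs in the 2 libraries together, and 6 of the 640 list genes are absent from the matrices. Each list's median ratio was placed among the medians of 10000 random lists matched on expression in 20 bins, as a description of these libraries.

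Shares of cells with a UMI of a gene were taken after each cell was thinned to 1000 UMIs. For genes that lay back toward Sham in TAC+ART, the TAC cells were split at random into 2 parts. One part chose the genes against Sham (a log2 ratio of 1 or more either way and at least 100 UMIs), and the other gave the ratio to TAC+ART. Mitochondrial, ribosomal, haemoglobin and sex-linked genes and Malat1 were left out of this choice. Markers of another class and genes far higher in another class were not left out, so free RNA of other cells may be among the chosen genes. The same steps were run on 50 simulations of groups that did not differ, with counting error as the only variation. On simulated data with 200 genes per comparison set to a known ratio, the intervals of fibroblast-like genes covered the true TAC over Sham ratio in 96.1% of 11587 genes.

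Groups, gene lists, markers, the naming rule and 17 alternative settings were fixed before the data were examined, and 2 settings were added after it was seen that barcodes end near 10000 UMIs and that some clusters are shallow. The share of Y-linked and other sex-linked UMIs served only as a check on the libraries. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.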

Results

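RNA of mouse ventricles was counted per droplet barcode in 3 libraries, Sham, TAC and TAC+ART, with 1 library of 3 pooled hearts per group. The sources do not say whether whole cells or nuclei were loaded, and barcodes are called cells below. The series concerns a search for drugs against cardiac fibrosis and names MD2 (gene Ly96), the co-receptor of Toll-like receptor 4, as a target. The Sham library held 3752 barcodes and 17710689 UMIs, with a median of 4310 UMIs per barcode (range 522 to 27924). The TAC library held 7413 barcodes and 37658150 UMIs, with a median of 4811 (774 to 46527). The TAC+ART library held 6856 barcodes and 33364667 UMIs, with a median of 4524.5 (828 to 26703). There were no replicate libraries, so the values below describe these 3 libraries. Levels are UMIs of a gene relative to all UMIs of the class (CPM). The intervals are 95% intervals for counting error and do not cover differences between hearts or preparations.

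The first comparison asked how the makeup of the ventricle differed between the groups. Macrophage-like cells made up 9.87% of the Sham library (8.92 to 10.9), 20.5% of the TAC library (19.5 to 21.4) and 16.1% of the TAC+ART library (15.2 to 17.0). Cardiomyocyte-like cells, the contracting muscle cells, made up 8.27% in Sham (7.40 to 9.22), 3.30% in TAC (2.89 to 3.75) and 5.71% in TAC+ART (5.16 to 6.30). Fibroblast-like cells, the main makers of matrix, were not a larger share in TAC, with 31.1% in Sham, 25.4% in TAC and 28.0% in TAC+ART. In each of these 3 classes the TAC+ART share lay between those of TAC and Sham.

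On the log2 scale, the share of macrophage-like cells was higher in TAC than in Sham by 1.05 (0.90 to 1.21) and the TAC+ART over TAC value was -0.34 (-0.45 to -0.24). The cardiomyocyte-like values were -1.33 (-1.57 to -1.09) and 0.79 (0.56 to 1.02), and the fibroblast-like values -0.29 (-0.38 to -0.20) and 0.14 (0.06 to 0.22). The size of the fibroblast-like values depended on the processing, with -0.50 and 0.25 among cells of at most 8000 UMIs, -0.52 and 0.34 with each library clustered alone, and -0.17 for TAC over Sham at the coarser clustering. Pericyte-like cells, which wrap small vessels, made up 10.4% in Sham, 5.29% in TAC and 7.04% in TAC+ART. Lymphatic endothelial-like cells made up 2.23%, 3.70% and 2.55%, endocardial-like cells 5.31%, 5.29% and 4.51%, and endothelial-like cells 28.7%, 30.6% and 29.95%. The endothelial-like TAC over Sham value of 0.09 turned to -0.25 at the finer clustering and to -0.05 with each library clustered alone. Among cells other than cardiomyocyte-like cells, macrophage-like cells were 10.8% in Sham, 21.2% in TAC and 17.1% in TAC+ART, and fibroblast-like cells 33.9%, 26.3% and 29.7%. Unnamed clusters held 1.90%, 4.27% and 3.78%.

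Few barcodes lay above 10000 UMIs (9 in Sham, 3 in TAC and 9 in TAC+ART) while 162, 405 and 282 lay within the 1000 UMIs below it, so the deepest cells are missing from each library. Cardiomyocyte-like cells had the highest median depth in Sham, 7501 UMIs against 5036 in TAC and 6005 in TAC+ART, and among cells of at most 8000 UMIs their TAC over Sham value was -0.81. Removing doublets left 0 epicardial-like cells of 6972 in TAC, with an upper interval limit of 0.053%, although 21 were there with doublets kept. The T or NK-like class held 53 cells of TAC without doublets and 89 with them, and these small classes were not compared.

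**Figure D1:**
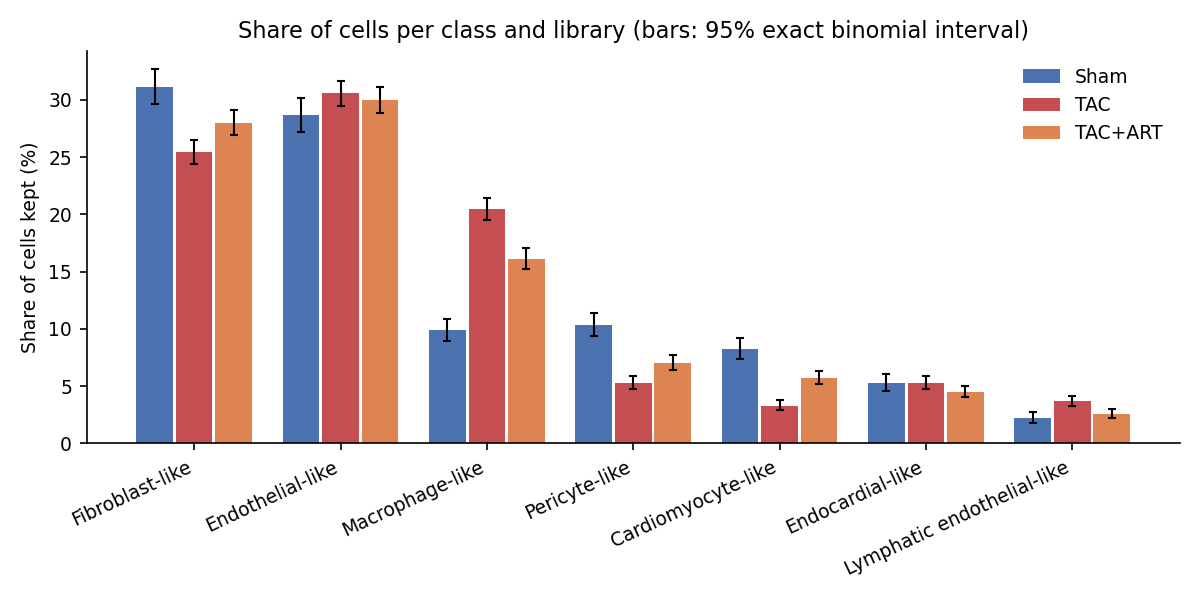
Share of cells (%, vertical axis) of 7 cell classes in the Sham, TAC and TAC+ART libraries, with 95% exact binomial intervals as bars. Macrophage-like cells reach 20.5% in TAC against 9.87% in Sham, and cardiomyocyte-like cells 3.30% against 8.27%.

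The main comparison asked how fibroblast-like cells of the pressure-loaded heart differed from those of Sham. Genes of the activated, matrix-producing fibroblast were far higher in the TAC library. Postn, which encodes the matrix protein periostin, stood at 1037 CPM in TAC against 56.4 in Sham, a log2 ratio of 4.20 (4.04 to 4.37). Col1a1 and Col3a1, the main fibrillar collagens, were higher by 2.31 (2.21 to 2.42) and 1.72 on the log2 scale. Of the 34 measured genes of the collagen and matrix list, 34 were higher in TAC, with a median of 1.36 (1.30 to 1.43), above all of the random lists. The sums behind these values held 5535010 UMIs in 1132 Sham cells and 10806362 UMIs in 1772 TAC cells, and the median depth per cell was 4614 and 6144 UMIs.

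The activated fibroblast list had the highest median, 2.06 (1.89 to 2.47), with 24 of 28 measured members higher in TAC, and 1.48 when each library was clustered alone. Several of its members lead the ranking of 4384 genes. Thbs4, a matrix thrombospondin, had 2 UMIs in Sham and stood at 92.0 CPM in TAC (log2 7.67, 6.13 to 11.04). Comp, another matrix protein of that family, was higher by 5.73, Cilp, a cartilage matrix protein, by 4.76, Ltbp2, a binding protein of microfibrils, by 4.24 and Meox1, a homeobox transcription factor, by 3.69. Adamtsl2, an extracellular protein that binds microfibrils, was higher by 3.68 and Arntl, the core clock activator BMAL1, by 3.70. Nppa, the atrial natriuretic peptide of muscle cells, was higher by 4.82, but it stood at 207 CPM in TAC fibroblast-like cells against 1358 in cardiomyocyte-like cells. Among matrix genes, Mfap4, a microfibril protein, was higher by 3.33 and Lox, which crosslinks collagen, by 3.24, while Dcn (decorin) differed by only 0.14 and Fbln1 (fibulin) by 0.38. Fap, a protease of the same activated list, was lower in TAC, 154 against 330 CPM.

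Genes at the low end included Grm8, a glutamate receptor, at 2.499 CPM in TAC against 113 in Sham (log2 -5.47, -6.11 to -4.94). Inmt, a methyltransferase, had -3.95, Ccbe1, a secreted factor of lymphatic growth, -3.50, A830012C17Rik -3.20, Mme, the surface peptidase neprilysin, -3.00, and Tll2, a metalloprotease, -2.83. Ptgfr, the prostaglandin F receptor, had -2.77, Col6a6, a collagen VI chain, -2.71, Kcnip1, a potassium channel subunit, -2.63, and Hlf, a clock output factor, -2.62. The resting fibroblast list as a whole was close to no difference, with a median of -0.04 and 12 of 20 members lower in TAC. Its members went both ways, with Abca6, a lipid transporter, at -2.08 and Gsn (gelsolin) and Pi16 higher by 0.77 and 0.76.

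Signalling lists were higher in TAC fibroblast-like cells in most of their members. NF-kB target genes had a median of 0.86 (20 of 22 higher), TGF-beta signalling 0.62 (23 of 27 higher) and immediate early and heat shock genes 0.92 (27 of 27 higher). The NF-kB and immediate early lists were also higher in TAC in macrophage-like (0.42 and 0.28) and endothelial-like cells (1.41 and 0.66). Neither was therefore particular to fibroblast-like cells. With 1 preparation per group, effects of tissue collection on these lists cannot be told apart from those of the load. Il6, an inflammatory cytokine, rested on 7 UMIs in Sham and 98 in TAC (log2 2.75). Tgfb1, the fibrogenic cytokine, was higher by 1.97 and Ccn2, a target of TGF-beta, by 3.20, while Tgfb2 had -0.67. Egr3 and Egr2, transcription factors of the immediate response, were higher by 2.48 and 2.35. The unfolded protein list had a median of 0.63 (19 of 24 higher), with Hspa5, the chaperone BiP, higher by 1.67 and Calr (calreticulin) by 1.90.

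RNA of the receptor complex of the series title did not differ in the same way. Protein levels, drug binding and pathway activity were not measured. Ly96 stood at 15.7 CPM in Sham, 14.7 in TAC and 14.4 in TAC+ART in fibroblast-like cells, from 87, 159 and 145 UMIs. Its ratios were -0.10 (-0.48 to 0.30) for TAC over Sham and -0.03 (-0.37 to 0.30) for TAC+ART over TAC, so no difference was detectable at this depth. After thinning, the intervals of its share of cells overlapped those of cardiomyocyte-like cells, taken as the level of free RNA. These ratios may therefore include free RNA from other cells. Tlr4, the receptor that MD2 joins, stood at 105, 99.02 and 106 CPM (-0.09, -0.23 to 0.06, and 0.10, -0.03 to 0.22). Cd14, which hands lipopolysaccharide to this complex, was near the limit of detection with 2.35, 3.89 and 3.68. The whole TLR4 and MD2 list had a median of -0.01 (-0.09 to 0.12) for TAC over Sham, with 15 of 31 measured members higher. By 1.5-fold or more, 8 members were higher and 0 lower, but random lists were not counted this way. The list shares Nfkb1, Nfkb2, Relb and Nfkbia with the NF-kB target list and Jun with the immediate early list. Its counts are therefore not separate from those lists. Nfkb2 and Nfkbia, an NF-kB subunit and the inhibitor it induces, were higher by 1.57 and 1.33. In GRCm38 coordinates Ly96 lies on chromosome 1 from 16688051 to 16709611, Tlr4 on chromosome 4 from 66827584 to 66930284 and Postn on chromosome 3 from 54361109 to 54391037.

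Different clusters held most fibroblast-like cells in the groups. Cluster 3 held 77.1% of those in TAC, 2.30% in Sham and 11.8% in TAC+ART, whereas cluster 2 held 3.78% in TAC, 55.5% in Sham and 67.2% in TAC+ART. Cluster 16, with Grm8, Inmt and Ccbe1 among its leading genes, held 13.3% in Sham, 0.56% in TAC and 3.80% in TAC+ART. Cluster 19, with Thbs4, Ltbp2, Cilp and Postn among its leading genes, held 2 cells of Sham, 94 of TAC and 20 of TAC+ART. Its median depth was 1888.5 UMIs. The ratios thus compare different mixes of clusters, and how far the highest and lowest genes rest on single clusters was not tested.

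**Figure D2:**
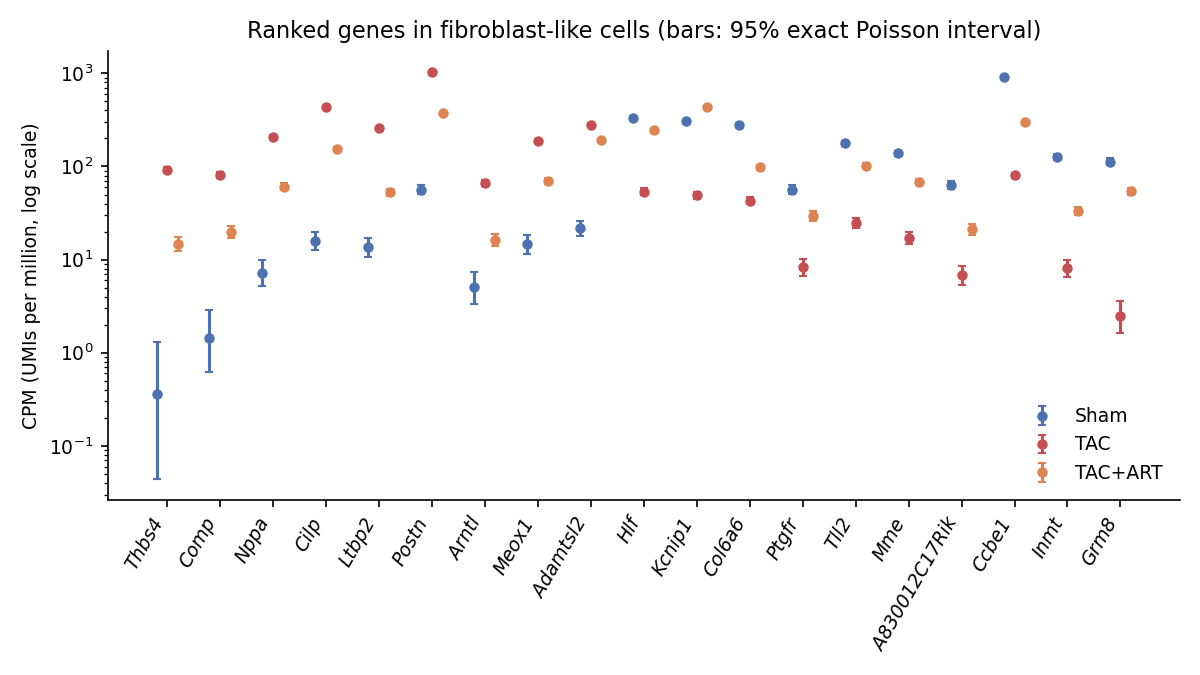
CPM (vertical log axis) in fibroblast-like cells of 9 of the 10 highest and of the 10 lowest ranked genes of TAC over Sham, with 1 point per library and 95% exact Poisson intervals. Postn stands at 56.4 in Sham, 1037 in TAC and 374 in TAC+ART.

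The next comparison asked how fibroblast-like cells differed with artesunate under the same load. Matrix and activation genes were lower in the TAC+ART library than in the TAC library and stood above Sham. Postn stood at 374 CPM against 1037 in TAC (log2 -1.47, -1.52 to -1.42), and Col1a1 at 446 against 716 (-0.68, -0.74 to -0.63). The collagen and matrix list had a median of -0.58 with 30 of 34 members lower, below all of the random lists, and the activated list had -1.42 (-1.46 to -0.85) with 21 of 29 lower, or -0.57 when each library was clustered alone. Against Sham these lists still stood 0.93 and 1.11 higher. TAC+ART sums held 10064082 UMIs in 1814 cells, with a median of 5337.5 UMIs per cell.

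The lowest of 4209 ranked genes was Timp1, an inhibitor of matrix metalloproteases, at 17.5 CPM against 111 in TAC and 8.85 in Sham (log2 -2.66). Thbs4 had -2.63, Mt2, a metallothionein, -2.61, Gm17268 -2.39, and both Serpina3n, a protease inhibitor of the acute phase, and Ltbp2 -2.29. Col12a1, a fibril-associated collagen, had -2.11, and both Errfi1, a feedback inhibitor of growth factor receptors, and Piezo2, a mechanosensitive channel, had -2.05. The 10 genes highest in TAC+ART over TAC were all lower in TAC than in Sham. Grm8 was higher by 4.41 (3.88 to 5.05), Kcnip1 by 3.14, Gm4956 by 2.48, Hlf by 2.19, Gsta3, a glutathione transferase, by 2.14, Tll2 by 2.02, Mme by 1.99, Ccbe1 by 1.90, Podn (podocan) by 1.79 and Fam13a by 1.78. The resting list had a median of 0.28 with 15 of 20 members higher, and Fap was higher by 1.06.

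NF-kB target genes had a median of -0.87 in TAC+ART over TAC (21 of 24 lower), immediate early and heat shock genes -0.86 (26 of 27 lower), the unfolded protein list -0.55 (18 of 24 lower) and TGF-beta signalling -0.39 (21 of 27 lower). Il6 had 98 UMIs in TAC and 8 in TAC+ART (-3.43), the chemokine Cxcl1 had -2.18 and Tgfb1 -1.44. Against Sham, the NF-kB list stood at 0.03 and the immediate early list at 0.24. The TLR4 and MD2 list had -0.12, with 22 of 31 members lower, which lies within the range of random lists (percentile 23.3). By 1.5-fold or more, 5 of its members were lower and 0 higher, with the same overlap of lists.

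Across all genes chosen for a difference of TAC from Sham, most lay back toward Sham in TAC+ART. In fibroblast-like cells, 651 genes chosen as higher in 1 random part of the TAC cells had a median TAC+ART over TAC of -0.55 against the other part, and 94.3% of them were lower. The 457 genes chosen as lower had a median of 0.80, and 95.6% were higher. Their medians against Sham were 0.81 and -0.53. Groups simulated without a difference gave 0.16 and 0.2 such genes on average. The simulations held counting error only, so they do not show how many genes would differ between hearts or preparations. Both parts of the TAC cells came from the same library, so a deviation of that library alone would also place these genes back toward Sham.

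**Figure D3:**
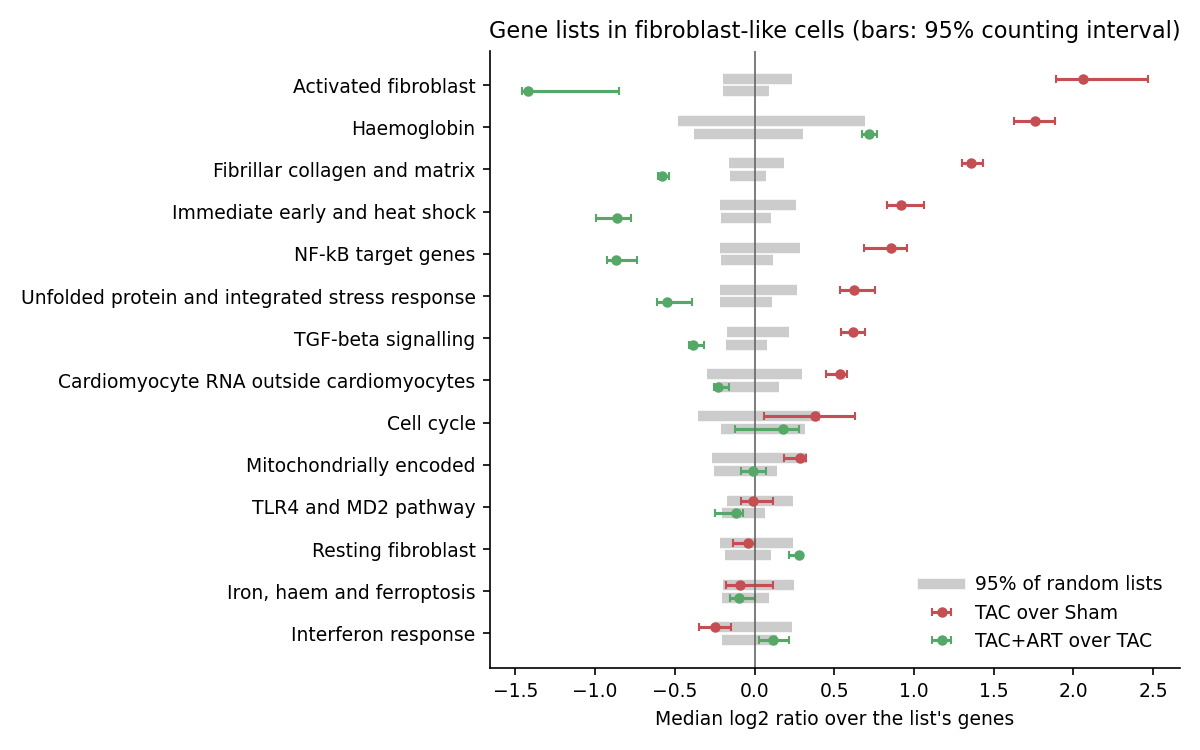
Median log2 ratio (horizontal axis) of 14 gene lists in fibroblast-like cells, TAC over Sham in red and TAC+ART over TAC in green, with 95% counting intervals and a grey band for 95% of random lists. The activated list stands at 2.06 and -1.42, and the TLR4 and MD2 list at -0.01 and -0.12.

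Shares of fibroblast-like cells with a UMI of Postn followed the sums. After thinning to 1000 UMIs, Postn was seen in 1.86% of fibroblast-like cells in Sham (1.15 to 2.82), 45.9% in TAC (43.5 to 48.2) and 19.4% in TAC+ART (17.6 to 21.3), and without thinning in 7.60%, 84.8% and 48.9%. In cardiomyocyte-like cells, which serve as the level of free RNA, it was seen in 0.997%, 23.5% and 7.84% after thinning and in 5.32%, 71.7% and 32.2% before, so Postn RNA outside its own class was itself more common in TAC. The median depths were 4614, 6144 and 5337.5 UMIs in fibroblast-like cells and 7501, 5036 and 6005 in cardiomyocyte-like cells. Col1a1 was seen in 11.7%, 44.1% and 32.8% of thinned fibroblast-like cells and 2.33%, 16.1% and 5.95% of cardiomyocyte-like cells. Without thinning the Col1a1 shares were 37.8%, 88.5% and 77.0% against 9.97%, 42.2% and 27.3%.

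Ly96 was seen in 1.41%, 1.58% and 1.10% of thinned fibroblast-like cells, with overlapping intervals, and in 0.332%, 1.30% and 1.08% of cardiomyocyte-like cells. The intervals of both classes overlapped in each library, so Ly96 in fibroblast-like cells was not shown to lie above the level of free RNA. Macrophage-like cells had more Ly96, 7.80% in Sham, 5.47% in TAC and 6.70% in TAC+ART. Tlr4 was seen in 9.01%, 8.69% and 8.88% of thinned fibroblast-like cells and in 12.3%, 19.1% and 25.7% of cardiomyocyte-like cells, which are therefore no background for it. Without thinning Ly96 was seen in 5.65%, 7.68% and 6.56% of fibroblast-like cells and Tlr4 in 29.2%, 35.8% and 35.1%. In cardiomyocyte-like cells the shares without thinning were 8.31%, 5.65% and 5.95% for Ly96 and 42.9%, 43.5% and 54.9% for Tlr4. Thinning left out 1 cell among these classes, an endothelial-like cell of TAC+ART.

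**Figure D4:**
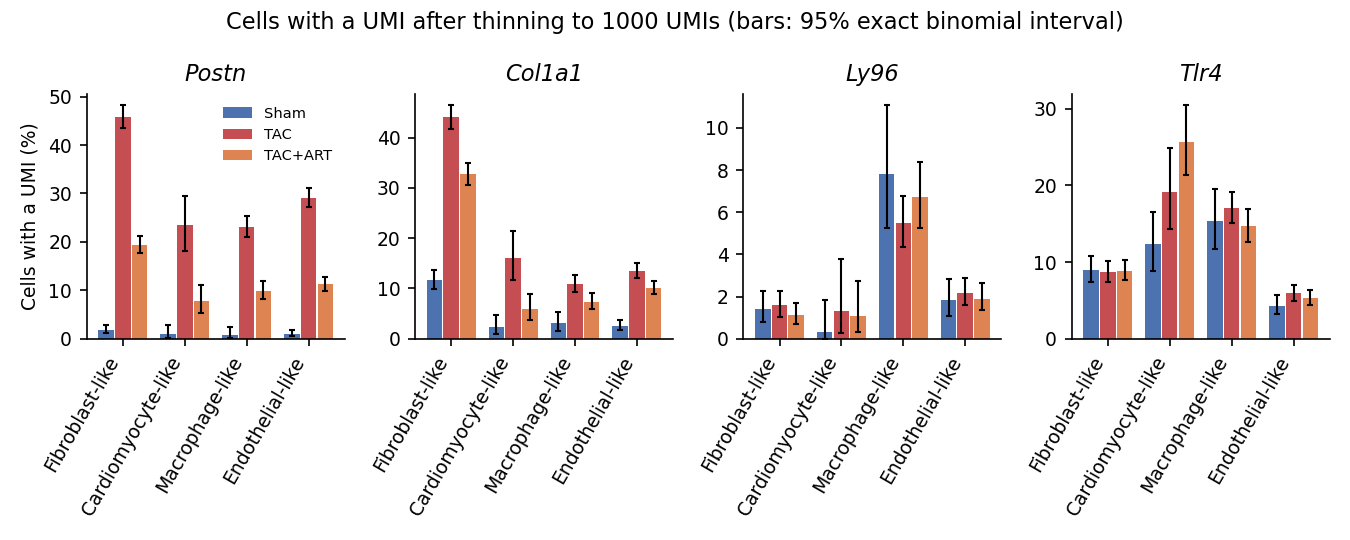
Share of cells (%, vertical axis) with at least 1 UMI of Postn, Col1a1, Ly96 or Tlr4 after thinning to 1000 UMIs, in 4 cell classes of the 3 libraries, with 95% exact binomial intervals. Postn reaches 45.9% of fibroblast-like cells and 23.5% of cardiomyocyte-like cells in TAC.

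The comparison of cardiomyocyte-like cells asked about the hypertrophic programme of the loaded muscle. Its genes were higher in TAC and lower again in TAC+ART. Nppa stood at 16.7 CPM in Sham, 1358 in TAC and 265 in TAC+ART (log2 6.33, 5.87 to 6.87, and -2.36, -2.50 to -2.22). Nppb, the B-type natriuretic peptide, was higher in TAC by 3.604 and Acta1, skeletal actin, by 4.62. Of the 21 measured genes of the hypertrophy list, 21 were higher in TAC (median 1.29), 21 were lower in TAC+ART than in TAC (median -1.09), and the median against Sham was 0.50. Myh7, the fetal myosin heavy chain, differed by 0.43 (0.30 to 0.56) and -0.60, and Myh6, the adult one, by 0.19 and -0.16.

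Other genes ranked high in TAC were Csmd1 (5.56, from 3 UMIs in Sham), Gm41505 (5.33), Cilp (5.31) and Postn (4.77). Csmd1, a complement control protein, turned to -1.49 with each library clustered alone. Cilp and Postn stood at 103 and 240 CPM here against 434 and 1037 in fibroblast-like cells. The low end held Ces1d, a carboxylesterase of lipid metabolism, at 28.4 against 278 CPM in Sham (-3.27), the chloride channel Clcn1 (-3.23), Gm37621 (-2.68), Ripor2 (-2.58) and Gm20532 (-2.53). In TAC+ART over TAC, Ces1d (2.55), Gm37320 (2.01), Ripor2 (1.90), Gm20532 (1.81) and Hs3st5, a heparan sulfate sulfotransferase (1.69), were highest. Csmd1 (-4.38, but 0.60 among cells of at most 5% mitochondrial UMIs), Nppa, Gm41505 (-2.04), Abra (-1.96), and the small heat shock protein Hspb1 (-1.89) were lowest.

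Energy genes were mostly higher in the TAC library. The oxidative phosphorylation list had a median of 1.64 (31 of 32 higher) and -0.96 in TAC+ART over TAC (30 of 32 lower), with Cox6c of complex IV at 2.07 and Ndufb8 of complex I at 2.35. Glycolysis had 0.76 (17 of 22 higher) and -0.43, with Gapdh at 2.73 and Hk2 (hexokinase) at -0.97, and fatty acid oxidation had 0.42 (18 of 29 higher) and -0.47, with Fabp3 at 2.11 and Ucp3 at -1.96. Adult contraction and ion handling had -0.46 (19 of 26 lower) and 0.27 (18 of 26 higher), both within the range of random lists (percentiles 11.5 and 88.9). Its members split, with the adrenergic receptor Adra1b at -2.13 and the potassium channel Kcnd2 at -1.35 while Tnni3 (troponin I) was higher by 1.45. Immediate early and heat shock genes had 1.38 and -1.12. Mitochondrially encoded genes moved the same way, 0.981% of cardiomyocyte-like UMIs in Sham, 2.40% in TAC and 1.34% in TAC+ART, and the nuclear RNA Malat1 the other way, with 12.3%, 9.03% and 10.5%. The ribosomal RNA Rn18s made up 0.51%, 1.70% and 1.46%. The makeup of the RNA per barcode thus differed between the libraries. Its part in the ratios of the energy and hypertrophy lists was not tested.

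Tlr4 was higher in TAC cardiomyocyte-like cells, 411 CPM against 154 in Sham (1.41, 1.21 to 1.62), and was at the same level in TAC+ART (ratio 0.00). Ly96 was at 14.3, 11.03 and 9.74, and Cd14 had 0, 2 and 7 UMIs. The TLR4 and MD2 list had -0.03 and -0.06. These cells numbered 301, 230 and 370, with 2099196, 1268778 and 2258370 UMIs. Cluster 12 held 71.8% of them in Sham and 22.2% in TAC, and cluster 17 held 10.3% and 47.8%. The ratios of this class therefore also compare different mixes of clusters. The median of all genes in this class was -0.13 for TAC over Sham.

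In macrophage-like cells the question was whether resident and recruited programmes differed. Genes of resident heart macrophages were lower in TAC and back near the Sham level in TAC+ART, with medians of -0.34 (11 of 16 lower) and 0.45 (13 of 16 higher), and -0.01 (-0.04 to 0.12) for TAC+ART over Sham. Timd4, a receptor for dying cells, stood at 182, 68.3 and 175 CPM and the chemokine Ccl24 differed by -1.42 and 0.94, while Lyve1 and Mertk, resident markers too, were higher in TAC by 0.71 and 0.72. Genes of recruited macrophages had 0.71 (15 of 18 higher) and 0.06 (9 of 18 higher). Against Sham, they still stood 0.90 higher in TAC+ART (13 of 16 higher). For TAC over Sham, Thbs1 had 3.82, from 2 UMIs in Sham, and Vcan (versican) 2.55. Ccr2, the receptor of incoming monocytes, did not differ within this class (-0.01). An unnamed cluster with neutrophil and monocyte markers, outside this class, held 7 cells of Sham, 46 of TAC and 18 of TAC+ART. In TAC+ART, Il1b, an inflammatory cytokine, stood at 9.73 CPM against 44.2 in TAC (-2.17), and Fos, an immediate early gene, had -3.59.

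NF-kB target genes had medians of 0.42 (19 of 26 higher) and -0.25 (20 of 27 lower), but Nfkbiz and Ccl2 were higher in TAC+ART than in TAC by 0.58 and 0.43. Immediate early and heat shock genes had 0.28 and -0.53, and in TAC+ART they stood below Sham (-0.475, 16 of 25 lower). The TLR4 and MD2 list had 0.11 (20 of 32 higher) and -0.14 (26 of 32 lower), within the range of random lists. Ly96 stood at 64.4, 69.8 and 72.8 CPM, Tlr4 at 160, 190 and 178 (0.24, 0.05 to 0.43) and Cd14 at 23.3, 51.6 and 35.3 (1.13 and -0.54). The ranking was led in TAC by Cilp (5.38), Postn (4.66), Nppa (4.35), Gm49839 (3.67) and Acta1 (3.51), of which Postn and Nppa stood at 249 and 273 CPM, below their levels in fibroblast- and cardiomyocyte-like cells. At the low end were Ablim3 (-3.75), Zfp366 (-3.73), Lsamp (-3.48, but 0.02 among cells of at most 5% mitochondrial UMIs), Prkd1 (-3.29) and Ccdc85a (-3.07). These 5 values rest mostly on cluster 23, 60 Sham cells that hold 78.4% to 89.5% of the macrophage-like UMIs of these genes in Sham and in which endothelial markers scored 1.879 against 2.736 for macrophage markers. All of the genes but Lsamp stood higher in endothelial-like cells of Sham, such as Ccdc85a at 1866 CPM against 213. With no filter on cells, where cluster 23 was not named macrophage-like, the values were -1.70, -0.92, -1.07, -1.49 and -1.09. In TAC+ART over TAC the growth factor Pdgfc (2.30), Gm16000 (2.13), Kctd16 (2.07), the interferon-induced GTPase Iigp1 (1.88) and Abcd2 (1.63) were highest, and the cadherin Fat3 (-2.08), the chaperone Hsph1 (-1.95), Fosl2 (-1.92), Arntl (-1.80) and Slc24a3 (-1.75) were lowest. Of the 359, 1427 and 1045 cells, cluster 9 held 47.9% in Sham and 55.3% in TAC+ART, and cluster 8 held 53.9% in TAC. Cluster 23 held 16.7% of the Sham cells and 0.07% of the TAC cells, and the macrophage-like share had 1.32 for TAC over Sham with no filter on cells.

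In endothelial-like cells, inflammatory and adhesion genes were higher in TAC and lower in TAC+ART. All 24 measured NF-kB target genes were higher in TAC (median 1.41), and 24 of 26 were lower in TAC+ART than in TAC (-1.04), leaving 0.07 against Sham. The adhesion molecule Icam1 stood at 50.3, 229 and 57.5 CPM, the chemokine Cxcl1 at 8.22, 48.2 and 3.82, and Selp and Sele, the selectins that catch leukocytes, were higher in TAC by 2.34 and 4.35, Sele from 2 UMIs in Sham. The endothelial activation list had medians of 1.22 (20 of 23 higher) and -0.76 (19 of 23 lower), while the capillary list stayed at -0.06 and 0.02.

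The immediate early and heat shock list had 0.66 (22 of 25 higher) and -0.96 (25 of 25 lower), with the nuclear receptor Nr4a1 (-2.81), Fosl2 (-2.03), Icam1 (-1.995), the kinase Sik1 (-1.96) and Nppa (-1.88) lowest in TAC+ART over TAC. The highest there were the kinase Map2k6 and Iigp1 (both 1.54), the clock repressor Cry2 (1.38), Cyp26b1, which degrades retinoic acid (1.32), and Hlf (1.32). The ranking of TAC over Sham held Cilp (4.93), Postn (4.70), Nppa (4.61), Acta1 (3.54) and Serpinf1 (3.38) at the top, at levels below those of their main classes. At the low end it held Hlf (-2.18), Cd247 (-1.99), Cry2 (-1.95), Dbp (-1.76) and Per3 (-1.58), of which Hlf, Cry2, Dbp and Per3 are genes of the circadian clock. The matrix list had 1.62 (32 of 33 higher) and -0.30 here, with Col1a1 at 131 CPM in TAC against 716 in fibroblast-like cells, and TGF-beta signalling had 0.12 and -0.08. Ly96 stood at 20.5, 21.9 and 22.7 and did not differ detectably, Tlr4 at 47.5, 72.2 and 65.0 (0.60, 0.37 to 0.85, and -0.15) and Cd14 at 1.28, 6.41 and 3.03. The TLR4 and MD2 list had -0.003 and -0.17 (22 of 31 lower), the second below the range of random lists (percentile 1.21). By 1.5-fold or more, 10 members were higher and 0 lower in TAC over Sham. For TAC+ART over TAC, 0 were higher and 9 lower by as much. The overlap with the NF-kB and immediate early lists holds here too, and random lists were not counted this way. The libraries held 1043, 2130 and 1941 of these cells.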

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

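The settings that left out cells above 8000 UMIs and clusters under 0.5 times the median depth were chosen after the data were seen, and the other 17 were planned. Over all settings, 126 values of shares of classes stayed within their counting interval, 12 moved and 2 reversed. Of list medians 1550 stayed, 125 moved and 1 reversed, and of ratios of named genes 10689 stayed, 549 moved and 18 reversed. Of shares of fibroblast-like cells with a UMI, 113 stayed and 31 moved, and of medians of genes chosen as higher or lower in TAC, 55 stayed, 49 moved and 0 reversed. No list median or ratio of a named gene moved beyond its interval when cells were thinned to the shallowest library. Random thinning leaves a gene's part of the class UMIs unchanged on average, so it could hardly have moved these values. Leaving out cells above 8000 UMIs moved 87 ratios of named genes and reversed 3, and moved 22 list medians and reversed 0. No share of a class moved when taken over cells other than cardiomyocyte-like. Except where a setting acts by its construction (thinning, or the choice of genes at a smaller ratio), the cause was not tested. No paired analysis was possible because each group had 1 library of pooled hearts. Depth limits genes with few UMIs, such as Ly96 and Cd14 with 87 and 13 UMIs in the fibroblast-like cells of Sham. Values below are log2 ratios of TAC over Sham, then of TAC+ART over TAC where a second one follows, or shares in percent. Chosen genes means those chosen as higher or lower in TAC, with their median for TAC+ART over TAC.

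Among cells of at most 8000 UMIs, the share of cardiomyocyte-like cells had -0.81 and 0.51, that of fibroblast-like cells -0.50 and 0.25, and the resident macrophage list -0.46 and 0.48. Chosen genes had -0.85 (higher) and 0.77 (lower) in cardiomyocyte-like cells, 0.81 (lower) in endothelial-like cells and -0.53 and 0.52 in macrophage-like cells. There Hba-a2 in cardiomyocyte-like cells turned to 0.027 for TAC+ART over TAC, and Lpl and Ttn in endothelial-like cells to 0.002 and 0.10 for TAC over Sham. Without clusters under 0.5 times the median depth, Ttn in endothelial-like cells turned to 0.078, Postn was seen in 43.3% of TAC fibroblast-like cells, and chosen genes had -0.51 (higher) in fibroblast-like and 0.76 (lower) in endothelial-like cells.

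At resolution 2, the share of endothelial-like cells turned to -0.25 and had 0.28 for TAC+ART over TAC, Eln and Ttn in that class turned to 0.12 and 0.021, Postn was seen in 2.95% of Sham fibroblast-like cells, and chosen genes had -0.54 (higher) in fibroblast-like cells. At resolution 0.5, the share of fibroblast-like cells had -0.17 and Ttn in endothelial-like cells 0.16. Chosen genes had -0.49 (higher) in fibroblast-like, -0.90 and 0.68 in cardiomyocyte-like, 0.75 (lower) in endothelial-like and -0.51 (higher) in macrophage-like cells.

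With each library clustered alone, the share of endothelial-like cells turned to -0.049, with 0.082 for TAC+ART over TAC, and that of fibroblast-like cells had -0.52 and 0.34. The activated list had 1.48 and -0.57, the resting list 0.013 and 0.18, and Csmd1 in cardiomyocyte-like cells turned to -1.49. Postn was seen in 2.87% of Sham and 42.8% of TAC fibroblast-like cells. Chosen genes had -0.53 and 0.78 in fibroblast-like cells, 0.53 (lower) in cardiomyocyte-like, 0.84 (lower) in endothelial-like and -0.51 (higher) in macrophage-like cells.

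The cells of cluster 23, mostly of Sham, were macrophage-like in the main analysis and not in the 3 settings that follow. With no filter on cells, the share of macrophage-like cells had 1.32, the resident macrophage list -0.50 and Ttn in endothelial-like cells 0.16, and chosen genes had -0.98 and 0.67 in cardiomyocyte-like cells and 0.83 (lower) in macrophage-like cells. With at least 1000 UMIs, these values were 1.31 for the share, -0.50 for the resident list, -0.48 for genes chosen as higher in endothelial-like cells and 0.83 for genes chosen as lower in macrophage-like cells. With at most 5% mitochondrial UMIs, the share of macrophage-like cells had 1.33, the resident list -0.51, and the matrix list in fibroblast-like cells -0.53 for TAC+ART over TAC. Csmd1 in cardiomyocyte-like cells turned to 0.60 for TAC+ART over TAC, and Ttn in endothelial-like and Lsamp in macrophage-like cells to 0.095 and 0.015 for TAC over Sham. Postn and Col1a1 were seen in 43.1% and 41.8% of TAC fibroblast-like cells, and chosen genes had -0.52 (higher) in fibroblast-like, -0.90 (higher) in cardiomyocyte-like and 0.88 (lower) in macrophage-like cells.

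With doublets kept, the resident list had -0.41, and the capillary list in endothelial-like cells turned to -0.009 and Col8a1 there to 0.34 for TAC+ART over TAC. Lpl and Ttn in that class turned to 0.021 and 0.18 for TAC over Sham, and Postn was seen in 2.85% of Sham and 43.1% of TAC fibroblast-like cells. Chosen genes had -0.80 and 0.64 in cardiomyocyte-like, -0.49 and 0.85 in endothelial-like and 0.67 (lower) in macrophage-like cells. Without the 10% of each class richest in cardiomyocyte RNA, Lpl and Ttn in endothelial-like cells turned to 0.05 and 0.10, the matrix list in fibroblast-like cells had -0.52 for TAC+ART over TAC, and Postn was seen in 40.9% of TAC fibroblast-like cells.

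With each cell weighing the same, Ttn in endothelial-like cells turned to 0.018, the matrix list in fibroblast-like cells had 1.53 and -0.62, and the resident list -0.49. Chosen genes then had -0.59 (higher) in fibroblast-like, -0.66 and 0.54 in cardiomyocyte-like and -0.48 (higher) in endothelial-like cells. Scaled by the median ratio, the lists for TAC+ART over TAC had -0.53 (matrix), 0.33 (resting) and -0.067 (TLR4 and MD2) in fibroblast-like cells and 0.52 (resident) in macrophage-like cells. Chosen genes had -0.50, -0.68 and -0.48 (higher) in fibroblast-, cardiomyocyte- and endothelial-like cells and -0.40 and 0.53 in macrophage-like cells. Scaled without mitochondrial, Malat1 and cardiomyocyte genes, genes chosen as higher in fibroblast-like cells had -0.54. With list members of at least 100 UMIs, the hypertrophy list had 1.94 and -1.27.

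Genes chosen at a log2 ratio of 0.5 had -0.41 and 0.42 in fibroblast-like, -0.56 and 0.35 in cardiomyocyte-like, -0.35 and 0.36 in endothelial-like and -0.33 and 0.27 in macrophage-like cells. Without thinning, the shares of fibroblast-like cells with a UMI in Sham, TAC and TAC+ART were 7.60%, 84.8% and 48.9% for Postn, 37.8%, 88.5% and 77.0% for Col1a1, 5.65%, 7.68% and 6.56% for Ly96, and 29.2%, 35.8% and 35.1% for Tlr4. Thinned to 500 UMIs, they were 30.5% in TAC and 12.0% in TAC+ART for Postn, 6.01%, 28.2% and 18.6% for Col1a1, 0.959% in TAC and 0.441% in TAC+ART for Ly96, and 5.04%, 4.23% and 4.96% for Tlr4.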

Other observations

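The tests of counting errors, of the share of cardiomyocyte-like cells and of the clock genes were chosen after the results were seen. The tests of a shift of the whole TAC library were chosen before their own values were seen but after the main results had been computed.

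Interferon-induced genes, which restrain viruses, were mostly lower in TAC in endothelial-, macrophage- and fibroblast-like cells. In endothelial-like cells their list had a median of -0.38 for TAC over Sham, with 24 of 27 members lower, and 0.38 for TAC+ART over TAC, with 25 of 28 higher. Ifit3b and Cmpk2 had -1.10 and -0.88 and then 1.09 and 0.87. The list had -0.35 in macrophage-like cells (24 of 29 lower) and 0.04 in TAC+ART over TAC (15 higher and 14 lower). Among its members there, Ifit3 had -1.52 and 1.38 and the RNA helicase Ddx60 -1.26 and 1.32. In fibroblast-like cells the list had -0.25 (19 of 28 lower) and 0.12. In cardiomyocyte-like cells it had -0.02 (-0.30 to 0.52) and -0.15 from only 8 and 14 measured members, which does not set them apart from the other classes. Most genes of the unfolded protein and integrated stress response were higher in TAC, with list medians of 0.94 in cardiomyocyte-like (14 of 17 higher), 0.47 in macrophage-like (19 of 22) and 0.33 in endothelial-like cells (18 of 24), and -0.48, -0.60 and -0.23 for TAC+ART over TAC. Hspa5 was higher in TAC by 1.76 in cardiomyocyte-like cells and by 1.03 in endothelial-like cells.

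Iron genes went both ways, and the list medians for TAC over Sham were -0.09 in fibroblast-like, 0.23 in cardiomyocyte-like, 0.06 in macrophage-like and 0.14 in endothelial-like cells, with -0.10, -0.23, -0.14 and -0.12 for TAC+ART over TAC. Macrophage-like cells of TAC had less Slc40a1, the iron exporter, and less Tfrc, which takes up transferrin, at -1.68 and -1.39, and Ftl1 (ferritin) was higher by 1.35. Fibroblast-like cells had less Slc7a11, the cystine importer that guards against ferroptosis, in TAC (-1.75) and more in TAC+ART (1.63 over TAC). Gpx4, which reduces lipid peroxides, was higher in TAC by 1.30 in these cells. Cell cycle genes had medians of 0.38 and 0.18 in fibroblast-like, -0.24 and 0.20 in macrophage-like, 0.16 and 0.10 in endothelial-like and -1.03 and 0.26 in cardiomyocyte-like cells, the last from 5 and 3 members. These medians leave out an unnamed cluster led by cell cycle genes, with macrophage and endothelial markers, which held 25 cells of Sham, 30 of TAC and 56 of TAC+ART. In pericyte-like cells the matrix list had 0.99 and -0.30, with Mfap5 at 3.42, TGF-beta signalling 0.09 and -0.10, and cardiomyocyte RNA 0.73 and -0.28.

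In fibroblast- and macrophage-like cells, genes that differed between TAC and Sham lay back toward Sham in TAC+ART. The 299 genes chosen as lower in TAC macrophage-like cells lay back less, with a median of 0.46 for TAC+ART over TAC (82.6% higher) and -1.17 left against Sham, and 0.83 for TAC+ART over TAC with no filter on cells. Counting errors that both ratios share, which would leave the median above -0.2, are argued against by the separate parts of the TAC cells. There, genes chosen as higher in TAC had medians of -0.55 (-0.58 to -0.54) and -0.47 (-0.50 to -0.45) in the 2 classes. The covariance of both ratios across genes was -0.213 and -0.125, against -0.0001 or closer to 0 in simulated groups that did not differ. The macrophage-like median missed the limit of -0.5 first set for counting errors. After it was seen, the limit was changed to an interval wholly below -0.2. Both parts come from the same TAC library, so a deviation of its hearts or preparation enters both ratios. Such a deviation alone would place the chosen genes back toward Sham in TAC+ART, and the split cannot exclude it. A shift of the whole TAC library, which was expected to give the chosen genes at least 0.8 of their TAC over Sham median in endothelial-like cells, remains open. The genes chosen in fibroblast-like cells showed 0.625 of it there, 0.655 in pericyte-like, 0.62 in macrophage-like and 1.362 in cardiomyocyte-like cells, and those chosen in macrophage-like cells 0.797, 0.822 in pericyte-like, 0.919 in fibroblast-like and 1.568 in cardiomyocyte-like cells. RNA freed from other cells in the droplets may account for part of that, since Postn was seen in 23.5% of thinned cardiomyocyte-like cells of TAC, and 1 library per group cannot separate a shift from an effect in every cell type. An effect of artesunate or of the load on these cells stays open as the biological explanation, and differences between the pooled hearts were not tested.

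Cardiomyocyte-like cells were a smaller share of the TAC library than of the Sham library, and TAC+ART lay between them. Removal by doublet score is argued against as the whole cause, since the log2 ratio of the shares was -1.27 with doublets kept. Removal of deep barcodes before deposit was expected to leave more cells just under the limit in TAC than in Sham, and the values run against it. Of cardiomyocyte-like cells, 20% of those in TAC (15.03 to 25.8) had 8000 UMIs or more against 42.9% in Sham (37.2 to 48.7) and 32.7% in TAC+ART, and among cells of at most 8000 UMIs the log2 ratio of the shares was still -0.81. It is not excluded, since few barcodes above the limit are in the matrices and a separate group of them would leave no trace. A loss of muscle cells in the loaded heart is 1 biological explanation that the design allows, and more cells of other classes would lower the share too. Neither was tested. An unnamed cluster with fibroblast and cardiomyocyte markers, outside this class, held 37 cells of Sham, 222 of TAC and 171 of TAC+ART.

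Clock genes differed between TAC and Sham, in opposite directions in fibroblast-like cells. There Arntl stood at 5.06 CPM in Sham, 66.7 in TAC and 16.3 in TAC+ART, while Dbp, which the clock drives in the other phase, stood at 154, 49.97 and 128 and Per3 at 293, 60.5 and 196. The median of the genes that go with Arntl lay above that of the genes that go with Dbp by 0.6 or more in all 5 classes, with 2.54 and -1.62 in fibroblast-like and 0.62 and -1.58 in endothelial-like cells. In macrophage-like cells the medians were -0.04 (1 of 4 higher) and -1.22, so the gap there came from the genes that go with Dbp alone, and Arntl itself had -0.07. Collection of the TAC hearts at another time of day and an effect of the load on the clock both predict this gap and cannot be told apart, since the genes were chosen for the pattern and times of collection were not used here.

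Mitochondrial RNA made up 0.826% of all UMIs in Sham, 0.985% in TAC and 0.902% in TAC+ART, and its list had medians for TAC over Sham of 0.29 in fibroblast-like, 1.16 in cardiomyocyte-like, 0.34 in macrophage-like and 0.17 in endothelial-like cells, with -0.01, -0.76, -0.19 and -0.08 for TAC+ART over TAC. Rn18s, a ribosomal RNA, made up 0.759%, 1.52% and 1.87% of all UMIs. Haemoglobin RNA made up 0.0492%, 0.139% and 0.209%, with list medians of 1.76, 2.39, 1.83 and 1.59 and then 0.72, 0.01, 0.97 and 0.46 in these classes. Cardiomyocyte RNA had 0.54 in fibroblast-like, 0.74 in macrophage-like and 0.41 in endothelial-like cells, and -0.23, -0.23 and -0.13 for TAC+ART over TAC. Y-linked genes made up 0.0479%, 0.0433% and 0.0454% of UMIs, and Xist had 15, 5 and 6 UMIs. Of 24 barcodes with 10000 UMIs or more or over 10% mitochondrial UMIs, 23 had a sequence that also occurs in another library, against 111 of the 17997 others.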
